A study of Danio rerio with 9 samples.

How the data were processed

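RNA from atrioventricular valve tissue of zebrafish was compared between 3 groups of 3 libraries each, uninjured, 48 h and 21 d after ablation of valve cells with 2.5 mM metronidazole for 6 h. Per the labels, tissue was laser-captured from heart cryosections, and polyA-selected directional libraries were made from 20 ng of RNA with a kit that carries molecular indexes and read as 2 × 75 bp. The labels do not say whether the molecular indexes were used to remove duplicates, whether the uninjured fish were bathed in the drug, at what time of day fish were collected, or whether libraries of a group came from separate fish.

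The authors trimmed reads with Trimmomatic 0.33 after FastQC 0.11.8, aligned them to danRer11 (GRCz11) with STAR 2.6.0c, counted them per gene with featureCounts 1.6.0 and normalised them with DESeq2 1.18.1, per the labels. The deposited table holds a normalised signal, the read count divided by a size factor and rounded to a whole number, for 21692 genes. This was tested on the values: median-of-ratios factors computed from the table differed by at most 0.11% between libraries, over 13019 genes above 0 in every library, while column totals ran from 15383031 to 21616553. The spacing of low values gave each library's size factor, between 0.851 and 1.398; in 7 simulated cases this estimate erred by at most 0.10%. The deposited values are therefore not raw counts, and no count model was fitted to them. Depth limits what can be measured for weakly expressed genes, and counting error was not modelled separately.

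The plan, written before the data were examined, assumed raw counts and named limma-trend for normalised values. Values were log2-transformed after adding 1. Genes with a value of at least 10 in at least 3 libraries were kept, 17891 in all. All 9 libraries entered 1 linear model in limma 3.58.1 under R 4.3.3 with a mean-variance trend, robust empirical Bayes and 6 residual degrees of freedom. The 3 comparisons were 48 h against uninjured, 21 d against uninjured and 21 d against 48 h, each two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Group values are means with the SD over 3 libraries on the deposited scale, and fold changes and SE come from the model.

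A set of 35 gene lists for cell types, pathways and processes was fixed before the data were examined, 3 of them by name pattern. The ribosomal pattern also takes in ribosomal protein kinases and rpl7l1. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation beside it, and adjusted over the 35 lists. The plan also named fry, a self-contained test that asks whether members change without comparing them with other genes. It was run but set no call. Named genes followed a rule fixed at the same time. They were the 6 highest and 6 lowest log2 fold changes among genes that passed, had a mean log2 CPM of at least 3 and did not overlap between groups, the 2 members with the smallest adjusted p of each list called by camera, and 14 genes fixed whatever their result. Where few members of a list changed, or where they did not match its name, members outside this rule (such as serpinh1a, serpinh1b, mgp and rps6ka5) were named after their values were seen. A gene that the rule names is not reported here. Gene symbols came from a reference table that matched 20518 of 21692 identifiers. The gene hbba1 has 2 identifiers, and reads of such near-identical copies cannot be assigned with certainty. The only coordinates available were for another genome build, so none are given.

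Overlaps between comparisons that share libraries were set beside independent lists and beside 20 simulated draws without any change. The model was tested on simulated data. Of 100 genes changed 2-fold at 48 h, 12 were called, and of 100 changed 4-fold 43 were called, with 8 of the unchanged genes called. At 21 d the numbers were 15, 44 and 5. In the same 2 runs, the other comparison with uninjured tissue had no simulated change, and there 1 and 2 genes were called. A 1.6-fold change of the mitosis list gave a camera adjusted p of 8.1e-07 and 0 other lists called. Simulated genes were drawn independently of each other, so these runs do not test list calls among correlated genes. In the data the estimated correlation within a list reached 0.70, for mitochondrially encoded genes. Alternatives covered scaling, pseudocount, filter, variance model, library weights, a replicate block, the groups in the fit and leaving out each library. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.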

Results

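Gene expression was measured in the atrioventricular valve tissue of zebrafish (Danio rerio) that were uninjured, or that had their valve cells ablated 48 h or 21 d earlier. Each group had 3 libraries, 9 in all, and each library came from material described as 2 hearts. Ablation used a 6 h bath in 2.5 mM metronidazole, a prodrug that becomes toxic in cells that carry a bacterial nitroreductase. The labels do not say whether the uninjured fish were bathed in the drug. Tissue was taken from heart cryosections by laser capture microdissection, in which a laser frees a chosen area of a section for RNA extraction. The values are normalised read counts per gene for 21692 genes, with column totals between 15383031 and 21616553. The spacing of the low values gave size factors, the reads behind a value of 1, between 0.851 and 1.398. Nothing in the labels says that the libraries of a group came from separate fish, so p-values measure the spread between these samples, which may be technical.

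Libraries of the 48 h group lay apart from the other 6 on the first principal component, which held 23.7% of the variance. Spearman correlations, taken across genes, ran from 0.896 to 0.925 within groups and from 0.844 to 0.922 between groups. Heart-muscle genes took 6.31% ± 0.419 (SD, n = 3) of the values at 48 h, against 8.33% ± 0.788 in uninjured tissue and 8.51% ± 0.761 at 21 d. Haemoglobin genes took 7.95% ± 2.97 of the values in uninjured tissue, 4.89% ± 1.74 at 48 h and 10.9% ± 1.74 at 21 d. Genes of the mitochondrial genome took 14.2% ± 0.423, 13.4% ± 3.09 and 14.0% ± 0.539 in the same order.

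The comparison of 48 h with uninjured tissue asked what differed soon after the ablation. Genes of mitosis and of macrophages rose, and genes of the valve-interstitial matrix and the circadian clock fell. Of 57 tested genes of mitosis, 33 rose and 0 fell (46 rose when adjusted over the list alone). Their median log2 fold change was 2.85 (camera adjusted p = 8.1e-24, and adjusted p = 0.0339 with an estimated correlation). The proliferation marker mki67 (ENSDARG00000091150) rose 6.3-fold, from 528 ± 175 to 3383 ± 1375 normalised counts (SD, n = 3; log2 fold change 2.65, SE 0.31, limma adjusted p = 3.0e-06). The nuclear import receptor kpna2 (ENSDARG00000038066) rose 32.2-fold, with a log2 fold change of 5.01 (SE 0.56, adjusted p = 1.1e-06). Among 48 genes of DNA replication, 10 rose (21 when adjusted over the list alone), with a median of 1.52 and a camera adjusted p of 4.6e-10. That call was lost at adjusted p = 0.0605 with an estimated correlation. The replication clamp pcna (ENSDARG00000054155) rose 2.88-fold, from 875 ± 296 to 2447 ± 300 (adjusted p = 1.8e-04).

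Macrophage markers were higher at 48 h in 27 of 39 tested genes, with 0 lower. Adjusted over the list alone, 30 rose and 2 fell, and the list's median was 2.07 (camera adjusted p = 3.0e-20, and adjusted p = 0.0134 with an estimated correlation). The perforin-like macrophage gene mpeg1.1 (ENSDARG00000055290) rose 6.27-fold, from 146 ± 67.9 to 860 ± 66.7 (log2 fold change 2.65, SE 0.37, adjusted p = 2.0e-05). The granulin gene grna rose 7.19-fold and the leukocyte plastin lcp1 rose 6.13-fold. Of 22 neutrophil genes, 5 rose (11 when adjusted over the list alone; camera adjusted p = 4.0e-06, and adjusted p = 0.114 with an estimated correlation). The metalloprotease adam8a, which stands in the matrix protease list too, rose 29.5-fold (adjusted p = 3.1e-08). The myeloperoxidase gene mpx averaged 183 ± 71.4 at 48 h and 39.7 ± 68.7 in uninjured tissue (adjusted p = 0.0264). Its call was lost without uninjured library 1 (adjusted p = 0.15) or 2 (0.138), and without 48 h library 1 (0.0886), 2 (0.0591) or 3 (0.0742). It was also lost with array weights (0.0743) and with only the 2 groups in the fit (0.05). Inflammatory cytokine genes rose in 9 and fell in 3 of 38 (13 and 3 when adjusted over the list alone; camera adjusted p = 2.6e-04, and adjusted p = 0.0339 with an estimated correlation). The macrophage growth factor il34 rose 5.5-fold, and il11a averaged 494 ± 145 at 48 h and 12 ± 12.5 in uninjured tissue (adjusted p = 4.3e-04).

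Interferon and antigen-presentation genes rose in 8 and fell in 1 of 41 (11 and 1 when adjusted over the list alone; camera adjusted p = 4.0e-06, and adjusted p = 0.226 with an estimated correlation). The antiviral GTPase mxa rose 10.6-fold. Folding and secretion genes rose in 13 and fell in 3 of 55 (16 and 5 when adjusted over the list alone; camera adjusted p = 1.5e-04, and adjusted p = 0.128 with an estimated correlation). The chaperone hspa5 rose 2.83-fold, while the phosphatase subunit ppp1r15a fell by 2.14 on the log2 scale. Matrix proteases and their inhibitors rose in 8 and fell in 4 of 30 (10 and 5 when adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.226 with an estimated correlation). That list's adjusted p was 0.054 without 48 h library 2. The gelatinase mmp2 fell by 1.55 on the log2 scale. Ribosomal protein genes had a median of 0.17 over 88 genes (camera adjusted p = 0.0157, and adjusted p = 0.644 with an estimated correlation). Of these, rpl7l1 rose and the kinases rps6kal and rps6ka5, which share the name pattern, fell, and 0 passed when adjusted over the list alone. The list's median turned to -0.04 (adjusted p = 0.91) without 48 h library 3. Its call was also lost without uninjured library 2 (adjusted p = 0.0542) or 3 (0.133) and without 48 h library 2 (0.0788). The call of rpl7l1 was lost without uninjured library 1 (adjusted p = 0.12) or 3 (0.0717) and without 48 h library 2 (0.098) or 3 (0.101). That of rps6kal was lost with equal column totals (adjusted p = 0.137), without uninjured library 2 (0.131) or 3 (0.079) and without 48 h library 1 (0.117) or 3 (0.0708).

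**Figure D1:**
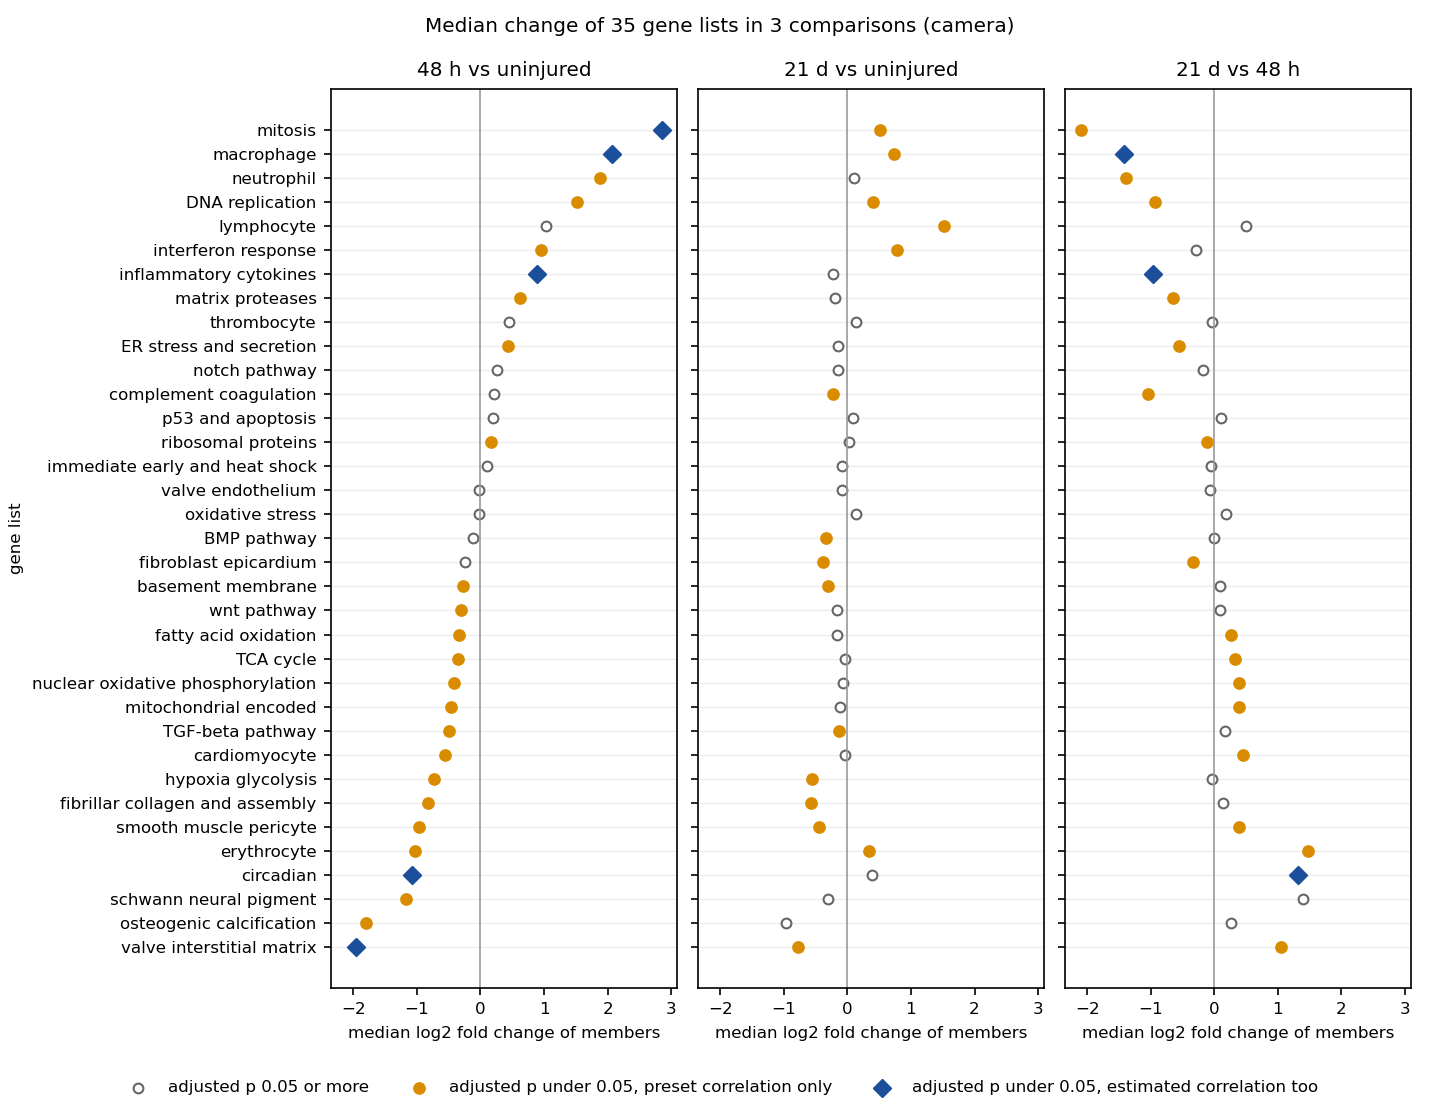
Median log2 fold change of the tested members of each of 35 gene lists (horizontal axis) in the 3 comparisons (panels); filled points passed camera at an adjusted p under 0.05, and diamonds also passed with an estimated correlation. At 48 h against uninjured tissue, mitosis genes had a median of 2.85 and valve-interstitial matrix genes a median of -1.96.

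Matrix genes of valve interstitial cells fell at 48 h in 11 of 27 (12 fell and 1 rose when adjusted over the list alone), with a median of -1.96. The camera adjusted p was 4.6e-10, and adjusted p = 0.0339 with an estimated correlation. Lumican, lum (ENSDARG00000045580), a collagen-binding proteoglycan, averaged 2450 ± 1106 in uninjured tissue and 69.3 ± 50.2 at 48 h (log2 fold change -5.41, SE 0.66, adjusted p = 4.9e-04). The elastin gene elnb (ENSDARG00000069017) averaged 2922 ± 1170 and 77 ± 14.4 (log2 fold change -5.17, SE 0.33, adjusted p = 1.9e-10). Decorin, dcn (ENSDARG00000012066), averaged 37479 ± 1839 and 10440 ± 1430 (log2 fold change -1.85, SE 0.14, adjusted p = 3.7e-09). Fibrillar collagen and assembly genes fell in 15 and rose in 2 of 37 (16 and 3 when adjusted over the list alone; camera adjusted p = 1.3e-06, and adjusted p = 0.114 with an estimated correlation). The collagen gene col1a1b fell from 46651 ± 4237 to 16572 ± 2412 (adjusted p = 7.4e-08), while the collagen chaperones serpinh1a and serpinh1b rose. Basement-membrane genes fell in 6 of 20 (7 when adjusted over the list alone; camera adjusted p = 0.00292, and adjusted p = 0.327 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.0526) and without 48 h library 2 (0.054). Bone and calcification genes fell in 3 of 14, namely dcn, sparc and mgp (3 fell and 2 rose when adjusted over the list alone). Of these, dcn stands in the matrix list too and sparc in the fibrillar collagen list, so these lists are not separate evidence for them. The bone list's camera adjusted p was 0.0366, with adjusted p = 0.226 with an estimated correlation. It was lost with no filter on low values (adjusted p = 0.121), without uninjured library 1 (0.0778) or 3 (0.0506) and without 48 h library 1 (0.0868).

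Camera also placed lists of muscle, red-cell and nerve or pigment genes lower, and none of these 4 calls held with an estimated correlation. Smooth-muscle and mural genes fell in 11 of 30 (12 fell and 1 rose when adjusted over the list alone; camera adjusted p = 4.6e-07, and adjusted p = 0.0605 with an estimated correlation). The elastin gene elnb stands in this list and in the matrix list. Heart-muscle genes fell in 22 and rose in 1 of 48 (26 and 2 when adjusted over the list alone), with a median of -0.56 (camera adjusted p = 3.2e-07, and adjusted p = 0.139 with an estimated correlation). The sarcomere gene tcap fell by 2.07 and the actin gene actc1a by 1.81 on the log2 scale. The atrial and ventricular light chain myl7 fell by 0.64 (adjusted p = 0.0244). Its call was lost with equal column totals (adjusted p = 0.214), quantile normalization (0.144), no robust step (0.112), a replicate block (0.0635), and without uninjured library 1 (0.113) or 48 h library 1 (0.0878). Red-cell genes fell in 6 and rose in 1 of 27 (7 and 1 when adjusted over the list alone; camera adjusted p = 7.8e-08, and adjusted p = 0.226 with an estimated correlation). The water channel aqp1a.1 fell by 1.93 on the log2 scale. The haemoglobin gene hbba1 stands under 2 identifiers whose reads cannot be told apart with certainty, with log2 fold changes of -1.03 and -0.87 that did not pass (adjusted p = 0.21 and 0.286). Schwann, neuronal and pigment genes had 1 member lower of 25 (1 when adjusted over the list alone), the pterin-synthesis gene gch2. The list's camera adjusted p was 0.0234, with adjusted p = 0.114 with an estimated correlation, and it was lost without uninjured library 3 (adjusted p = 0.0603) or 48 h library 2 (0.054).

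Signalling genes went both ways at 48 h. Of 36 genes of the TGF-beta pathway, 7 fell and 2 rose (10 and 2 when adjusted over the list alone; camera adjusted p = 0.00545, and adjusted p = 0.147 with an estimated correlation). The ligand tgfb1b (ENSDARG00000034895) rose 3.44-fold, from 341 ± 124 to 1129 ± 106 (log2 fold change 1.78, SE 0.32, adjusted p = 4.3e-04). The matrix genes postnb and tgfbi fell by 2.44 and 1.71 on the log2 scale. The signal transducer smad3b fell by 1.47 (adjusted p = 0.00806, and 0.0701 without uninjured library 2). The related tgfb1a (0.28), tgfb2 (-0.81), tgfb3 (-0.06) and smad3a (-0.58) did not pass, with adjusted p = 0.498, 0.091, 0.908 and 0.144. Without 48 h library 1, tgfb2 passed at adjusted p = 0.0117 and smad3a at 0.0451. With array weights tgfb2 passed at 0.0336. Wnt pathway genes fell in 3 and rose in 1 of 38 (5 and 1 when adjusted over the list alone; camera adjusted p = 0.0354, and adjusted p = 0.228 with an estimated correlation). The secreted antagonist frzb fell by 1.22 on the log2 scale. The list's call was lost with equal column totals (adjusted p = 0.0726), quantile normalization (0.0548), no filter (0.0541), and without uninjured library 2 (0.0787) or 3 (0.0924) or 48 h library 3 (0.0534).

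Metabolic and clock genes were lower at 48 h. Glycolysis and hypoxia-responsive genes fell in 23 and rose in 2 of 50 (25 and 3 when adjusted over the list alone; camera adjusted p = 5.8e-10, and adjusted p = 0.0983 with an estimated correlation). The oxygen-sensing prolyl hydroxylase egln3 (ENSDARG00000032553) averaged 4091 ± 318 in uninjured tissue and 453 ± 127 at 48 h (log2 fold change -3.21, SE 0.27, adjusted p = 1.7e-08). Circadian clock genes fell in 15 and rose in 1 of 35 (17 and 1 when adjusted over the list alone), with a median of -1.08 (camera adjusted p = 5.3e-08, and adjusted p = 0.0134 with an estimated correlation). The clock repressor per1b (ENSDARG00000012499) averaged 1781 ± 183 and 216 ± 31.8 (adjusted p = 6.8e-09). Fatty-acid oxidation genes fell in 7 and rose in 1 of 37 (12 and 1 when adjusted over the list alone; camera adjusted p = 0.0046, and adjusted p = 0.129 with an estimated correlation). The carnitine palmitoyltransferase cpt1b fell by 2.00 on the log2 scale. Citric-acid cycle genes fell in 5 of 31 (5 when adjusted over the list alone; camera adjusted p = 4.5e-04, and adjusted p = 0.327 with an estimated correlation). That call was lost with equal column totals (adjusted p = 0.0513) and quantile normalization (0.125). Nuclear genes of oxidative phosphorylation fell in 12 of 88 (12 when adjusted over the list alone; camera adjusted p = 4.0e-06, and adjusted p = 0.379 with an estimated correlation), a call lost without 48 h library 1 (adjusted p = 0.0884). Mitochondrially encoded genes fell in 2 of 13, mt-nd1 and mt-nd5 (4 when adjusted over the list alone; camera adjusted p = 0.00964, and adjusted p = 0.467 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.661) and without 48 h library 1 (0.256). The calls of mt-nd1 and mt-nd5 were lost with equal column totals (adjusted p = 0.0978 and 0.183), quantile normalization (0.212 and 0.285) and no robust step (0.129 and 0.219). They were also lost without uninjured library 2 (0.0899 and 0.085), 48 h library 1 (0.0531 and 0.0519) or 48 h library 3 (0.0588 and 0.103). The growth hormone gene gh1 (ENSDARG00000038185) averaged 38018 ± 2033 in uninjured tissue and 463 ± 209 at 48 h (log2 fold change -6.45, SE 0.24, adjusted p = 6.3e-13). The insulin-like growth factor binding protein igfbp1a averaged 38696 ± 17542 and 934 ± 366 (log2 fold change -5.34, SE 0.43, adjusted p = 2.0e-04).

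**Figure D2:**
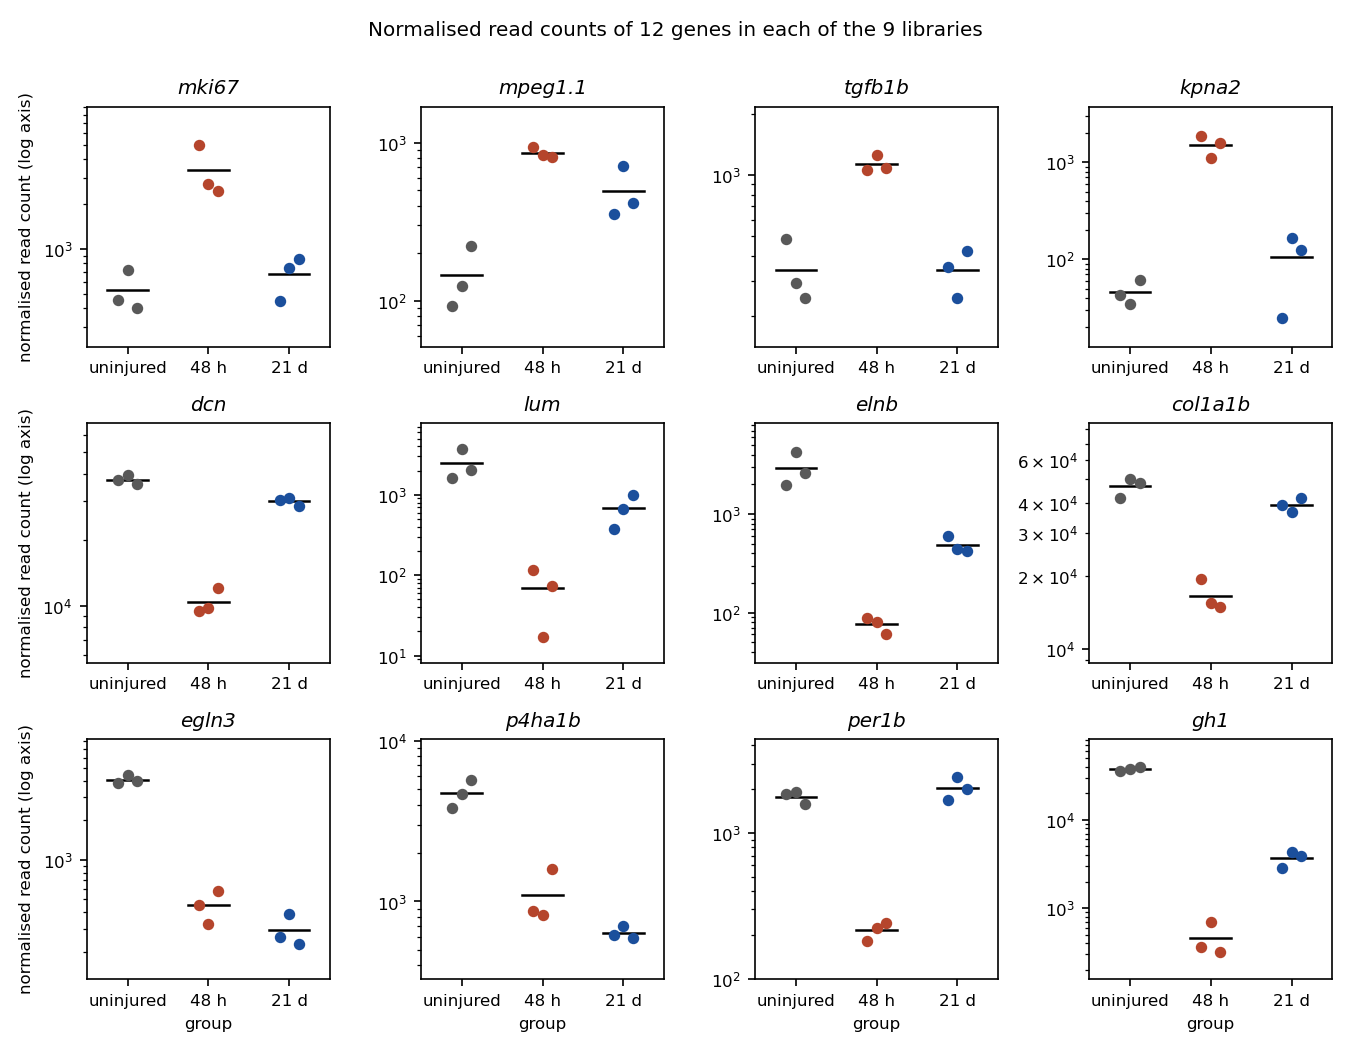
Normalised read counts (log axis) of 12 genes in each of the 9 libraries, as points, with the group mean as a line, for uninjured tissue, 48 h and 21 d after ablation. The 3 libraries of the 48 h group lie above the uninjured ones for mki67, mpeg1.1, tgfb1b and kpna2 and below them for the other 8 genes.

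The remaining 10 lists did not pass camera at 48 h, and in several of them single members changed. Endothelial and valve-endothelial genes rose in 6 and fell in 5 of 29 (8 and 5 when adjusted over the list alone), with a median of -0.02 and adjusted p = 0.357. The flow-responsive factor klf2a fell by 0.76 (adjusted p = 0.00631), a call lost with equal column totals (0.121) and quantile normalization (0.105). The valve transcription factor nfatc1 had a log2 fold change of 0.66 that did not pass (adjusted p = 0.0896). It passed with equal column totals (adjusted p = 0.0207), quantile normalization (0.0337) and without uninjured library 3 (0.0217). The receptor notch1b had a log2 fold change of -0.01 (adjusted p = 0.984). Fibroblast and epicardial genes rose in 9 and fell in 8 of 41 (11 and 10 when adjusted over the list alone; adjusted p = 0.937). BMP genes rose in 3 of 28 (3 when adjusted over the list alone; adjusted p = 0.656) and Notch genes in 0 of 24 (0 when adjusted over the list alone; adjusted p = 0.236). Complement and coagulation genes rose in 5 and fell in 3 of 26 (8 and 4 when adjusted over the list alone; adjusted p = 0.162). Lymphocyte markers rose in 2 of 20 (2 when adjusted over the list alone; adjusted p = 0.144), and thrombocyte markers rose in 2 and fell in 2 of 13 (2 and 2 when adjusted over the list alone; adjusted p = 0.176). Apoptosis and p53 genes rose in 3 and fell in 7 of 44 (3 and 7 when adjusted over the list alone; adjusted p = 0.59), with a median of 0.19 but a mean of -0.07. Oxidative-stress genes rose in 3 and fell in 5 of 43 (4 and 7 when adjusted over the list alone; adjusted p = 0.314). Immediate-early and heat-shock genes rose in 8 and fell in 10 of 48 (9 and 11 when adjusted over the list alone; adjusted p = 0.712), with a median of 0.11 and a downward camera direction.

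Over all 17891 tested genes, 794 rose and 1133 fell at 48 h against uninjured tissue, 1927 in total (limma-trend, adjusted p under 0.05), of which 639 and 821 changed at least 2-fold. The count of higher genes was 521 without 48 h library 2 and 514 without 48 h library 3. Values of the 2 groups did not overlap for 27.2% of genes, where chance gives 10%. With equal column totals the median of all genes moved to 0.28 and the split became 1348 higher and 653 lower, so directions hold relative to the deposited scaling.

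At 21 d against uninjured tissue, fewer genes passed, and the question was what still differed. Hypoxia-responsive genes and matrix genes were lower, and macrophage genes higher, though 0 of the 15 lists called by camera passed with an estimated correlation. The self-contained test fry, which does not compare members with other genes, passed some of these 15 lists and not others. Its adjusted p was 0.0151 for the hypoxia list and 0.198 for interferon genes. Glycolysis and hypoxia-responsive genes fell in 11 of 50 (23 when adjusted over the list alone; camera adjusted p = 1.4e-13, and adjusted p = 0.0945 with an estimated correlation). The gene egln3 averaged 293 ± 83.2 at 21 d (log2 fold change -3.83, SE 0.27, adjusted p = 1.2e-08), and the collagen prolyl hydroxylase p4ha1b (ENSDARG00000071082) fell from 4717 ± 935 to 637 ± 58.3 (adjusted p = 1.6e-07). Fibrillar collagen and assembly genes fell in 7 of 37 (7 when adjusted over the list alone; camera adjusted p = 2.3e-14, and adjusted p = 0.0945 with an estimated correlation). Those that fell were hydroxylases, oxidases and processing factors such as plod1a, p4ha1b and loxa, not collagen chains. Of these, p4ha1b stands in the hypoxia list too, so the 2 lists are not separate evidence for it. Valve-interstitial matrix genes fell in 3 of 27 (7 when adjusted over the list alone; camera adjusted p = 1.3e-06, and adjusted p = 0.0945 with an estimated correlation). The gene elnb averaged 484 ± 98.2 (log2 fold change -2.53, SE 0.33, adjusted p = 7.0e-05). The proteoglycan vcanb fell by 1.17, a call lost without uninjured library 3 (adjusted p = 0.0802) or 21 d library 1 (0.068). Smooth-muscle genes fell in 2 of 30 (3 when adjusted over the list alone; camera adjusted p = 9.6e-06, and adjusted p = 0.11 with an estimated correlation). The 2 were pdgfrb and elnb, and elnb stands in the matrix list too. Fibroblast and epicardial genes fell in 3 and rose in 1 of 41 (9 and 2 when adjusted over the list alone; camera adjusted p = 9.1e-06, and adjusted p = 0.0945 with an estimated correlation). The gene gh1 averaged 3727 ± 764 at 21 d (log2 fold change -3.37, SE 0.24, adjusted p = 7.5e-08).

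Macrophage genes rose at 21 d in 5 of 39 (9 rose and 1 fell when adjusted over the list alone; camera adjusted p = 3.1e-06, and adjusted p = 0.0945 with an estimated correlation). The gene mpeg1.1 averaged 492 ± 191 (log2 fold change 1.78, SE 0.37, adjusted p = 0.011). Its call was lost without uninjured library 1 (adjusted p = 0.0656) or 2 (0.0534) or 21 d library 2 (0.104). Interferon genes rose in 1 of 41, mxa (5 when adjusted over the list alone; camera adjusted p = 4.4e-06, and adjusted p = 0.309 with an estimated correlation). The call of mxa was lost without uninjured library 2 (adjusted p = 0.0685) or 21 d library 2 (0.0994). Camera also placed mitosis (adjusted p = 5.4e-04), DNA replication (0.0075), lymphocyte (0.0181) and red-cell genes (0.0442) higher, with 0 members called in each, and adjusted p = 0.33, 0.331, 0.238 and 0.666 with an estimated correlation. It placed basement-membrane (adjusted p = 0.0075), BMP (0.00852), TGF-beta (0.028) and complement genes (0.0399) lower, with 0, 0, 1 and 0 members called, and adjusted p = 0.448, 0.255, 0.309 and 0.179 with an estimated correlation. The single member called was ctgfb, a growth factor induced by TGF-beta, which fell by 2.05 (adjusted p = 0.00188). Adjusted over the list alone, the members that passed were 0 each for the 4 higher lists and 0 for basement membrane, 2 lower for BMP, 4 lower for TGF-beta and 2 lower and 1 higher for complement. Leaving out libraries ended several of these calls. Red-cell genes lost theirs without uninjured library 1 (adjusted p = 0.874) or 3 (0.142) and without 21 d library 1 (0.277) or 3 (0.152). DNA replication lost it without uninjured library 1 (0.128), lymphocyte genes without 21 d library 2 (0.0872), and basement membrane (0.052) and BMP genes (0.0626) without uninjured library 3. TGF-beta genes lost it without uninjured library 1 (0.0641) or 21 d library 1 (0.0803) or 2 (0.091) and under quantile normalization (0.0661). Complement genes lost it without uninjured library 1 (0.128), 48 h library 2 (0.0642) or 21 d library 2 (0.153), under quantile normalization (0.0734) and with array weights (0.0778).

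The other 20 lists did not pass at 21 d, among them circadian (adjusted p = 0.0657), bone (0.0504), endothelial (0.276) and heart-muscle genes (0.472), and matrix proteases had a median of -0.19 with a mean of 0.05 (adjusted p = 0.455). Among the genes fixed beforehand, tgfb1b averaged 340 ± 89 at 21 d, with a log2 fold change of 0.02 against uninjured tissue (adjusted p = 0.989). The log2 fold changes of tgfb1a (-0.39), tgfb2 (-0.01), tgfb3 (0.10), smad3a (-0.13), smad3b (0.10), nfatc1 (0.25), klf2a (-0.18), notch1b (0.12), myl7 (0.08), pcna (0.20) and hbba1 (0.41 and 0.54) did not pass either. Nor did mpx (3.48, SE 1.47), which passed at 5.78 without uninjured library 3 (adjusted p = 0.0387). It averaged 67 ± 52.8 at 21 d and 39.7 ± 68.7 in uninjured tissue. With an SD above the uninjured mean, its log2 fold change depends strongly on which low-value libraries are in the fit. The nuclear receptor rorcb rose 4.64-fold (adjusted p = 1.3e-06) and the glycogen-targeting phosphatase subunit ppp1r3aa fell by 3.67 on the log2 scale (adjusted p = 1.6e-07). In all, 93 genes rose and 167 fell, 260 in total (limma-trend, adjusted p under 0.05), and 17.9% of genes did not overlap between the groups, where chance gives 10%. The total was 427 with only these 2 groups in the fit. It was 141, 107 and 172 without uninjured library 1, 2 and 3, and 140, 134 and 129 without 21 d library 1, 2 and 3. The genes higher among these were 50, 38 and 71, and 38, 28 and 33, in the same order.

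From 48 h to 21 d, macrophage and inflammatory genes fell and circadian genes rose, the 3 lists whose calls held with an estimated correlation. Mitosis genes were called lower and valve-interstitial matrix genes higher with the preset correlation alone, and the fibrillar collagen and basement-membrane lists did not pass (adjusted p = 0.726 and 0.332). Mitosis genes fell in 21 of 57 (32 when adjusted over the list alone; camera adjusted p = 2.7e-16, and adjusted p = 0.0691 with an estimated correlation), with mki67 at 683 ± 212 at 21 d. DNA replication genes fell in 6 of 48 (7 fell and 1 rose when adjusted over the list alone; camera adjusted p = 3.1e-05, and adjusted p = 0.184 with an estimated correlation). Macrophage genes fell in 19 and rose in 3 of 39 (25 and 3 when adjusted over the list alone; camera adjusted p = 5.6e-12, and adjusted p = 0.03 with an estimated correlation). Inflammatory cytokine genes fell in 12 and rose in 2 of 38 (14 and 2 when adjusted over the list alone; camera adjusted p = 4.2e-05, and adjusted p = 0.03 with an estimated correlation). The cytokine-signalling inhibitor socs3b fell by 3.26 on the log2 scale (adjusted p = 2.5e-05). Neutrophil genes fell in 8 of 22 (10 when adjusted over the list alone; camera adjusted p = 3.5e-05, and adjusted p = 0.179 with an estimated correlation). Circadian genes rose in 15 and fell in 1 of 35 (21 and 1 when adjusted over the list alone; camera adjusted p = 5.6e-12, and adjusted p = 0.00768 with an estimated correlation), with nr1d2a 8.09-fold higher. Valve-interstitial matrix genes rose in 9 of 27 (10 when adjusted over the list alone; camera adjusted p = 7.6e-05, and adjusted p = 0.137 with an estimated correlation), among them dcn (2.88-fold) and elnb (6.22-fold).

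Heart-muscle genes rose from 48 h to 21 d in 23 and fell in 4 of 48 (camera adjusted p = 8.5e-06, and adjusted p = 0.249 with an estimated correlation), and red-cell genes rose in 7 of 27 (1.2e-11, and 0.196 with an estimated correlation). Nuclear oxidative phosphorylation genes rose in 9 and fell in 1 of 88 (camera adjusted p = 6.8e-05, and adjusted p = 0.508 with an estimated correlation). Folding and secretion genes fell in 17 and rose in 3 of 55 (2.6e-06, and 0.106 with an estimated correlation), matrix proteases fell in 10 and rose in 2 of 30 (0.0173, and 0.257), and complement genes fell in 10 and rose in 4 of 26 (0.00562, and 0.0965). Adjusted over the list alone, the counts were 27 higher and 5 lower for heart muscle, 15 and 1 for red cells, 9 and 1 for oxidative phosphorylation, 5 and 25 for folding, 4 and 12 for proteases and 4 and 15 for complement. Camera also called 6 lists with an adjusted p above 0.001 and adjusted p from 0.257 to 0.744 with an estimated correlation. These were smooth muscle, fatty-acid oxidation, citric-acid cycle and mitochondrially encoded genes, which were higher, and fibroblast and ribosomal protein genes, which were lower. Adjusted over the list alone, 7 rose and 1 fell in smooth muscle, 8 and 1 in fatty-acid oxidation, 5 and 0 in the citric-acid cycle, 2 and 0 among mitochondrial genes, 4 and 11 among fibroblast genes and 0 among ribosomal genes. Equal column totals ended the calls of smooth muscle (adjusted p = 0.0621), fatty-acid oxidation (0.208), citric-acid cycle (0.0611) and mitochondrial genes (0.104). Quantile normalization ended the same 4 calls (adjusted p = 0.0676, 0.0811, 0.0553 and 0.748), and a stricter filter ended that of fatty-acid oxidation (0.0586). Without 48 h library 1 the adjusted p was 0.2, 0.0797, 0.068 and 0.507 for these 4, 0.0637 for fibroblast genes and 0.371 for oxidative phosphorylation. Without 48 h library 2 it was 0.171 for ribosomal genes, and without 48 h library 3 it was 0.0912 for fatty-acid oxidation and 0.609 for ribosomal genes, whose median turned from -0.12 to 0.08. Without 21 d library 1 it was 0.204 for smooth muscle, 0.111 for fatty-acid oxidation, 0.0577 for mitochondrial and 0.076 for ribosomal genes. Without 21 d library 2 it was 0.0796 for fibroblast and 0.202 for ribosomal genes, and without 21 d library 3 it was 0.0766 for fatty-acid oxidation and 0.0603 for mitochondrial genes. Among the 16 lists that did not pass, fibrillar collagen and assembly genes rose in 7 and fell in 7 of 37 (9 and 11 when adjusted over the list alone; adjusted p = 0.726), with a median of 0.13 and a mean of -0.18. The 7 that rose were sparc and collagen chains such as col1a1b, and the 7 that fell were chaperones and modifying enzymes such as serpinh1a and plod1a. The hypoxia list had a median of -0.04 with an upward camera direction (adjusted p = 0.416), and the bone list a median of 0.26 with a mean of -0.07 (adjusted p = 0.416).

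The ligand tgfb1b fell from 48 h to 21 d by 1.76 on the log2 scale (SE 0.32, adjusted p = 5.2e-04), pcna fell by 1.33 (adjusted p = 8.4e-04) and smad3b rose 2.97-fold (adjusted p = 0.00523). The heart-muscle gene myl7 rose 1.64-fold (adjusted p = 0.0126, 0.0727 without 21 d library 1, 0.103 with equal column totals and 0.076 without the robust step) and klf2a rose 1.5-fold (adjusted p = 0.0403). The call of klf2a was lost with equal column totals (0.321), quantile normalization (0.192), only the 2 groups in the fit (0.0576), without uninjured library 3 (0.0527), without 48 h library 2 (0.135) or 3 (0.081), and without 21 d library 1 (0.051), 2 (0.138) or 3 (0.132). The log2 fold changes of tgfb1a (-0.67), tgfb2 (0.80), tgfb3 (0.16), smad3a (0.45), nfatc1 (-0.41), notch1b (0.13), mpeg1.1 (-0.87), mpx (-1.68) and hbba1 (1.28 and 1.57) did not pass. Of these, tgfb1a passed with equal column totals (adjusted p = 0.00851), quantile normalization (0.0282) and no robust step (0.0455). It also passed without 48 h library 3 (adjusted p = 0.0304), tgfb2 without 48 h library 1 (0.0131) and hbba1 at 1.57 without uninjured library 2 (0.0231), as did tgfb2 (0.048) and hbba1 (0.0446) with array weights. This hbba1 identifier also passed without the robust step (adjusted p = 0.00864) and with only the 2 groups in the fit (0.0374). In all, 980 genes rose and 788 fell, 1768 in total, and 27.3% of genes did not overlap, where chance gives 10%. With equal column totals the median of all genes moved to -0.24 and the split became 605 higher and 1281 lower. The total was 1144 without 21 d library 1, with 622 higher and 522 lower. The count of lower genes was 520 without 48 h library 2 and 497 without 48 h library 3.

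Genes that moved at 48 h and moved back by 21 d numbered 1069. Of these, 407 rose and then fell, where independent lists would share 35, and 662 fell and then rose, where independent lists would share 62.1. Unchanged groups simulated with the same shared libraries gave a mean of 0.05 such genes over 20 draws. Among the genes called at 48 h, 855 were not called from 48 h to 21 d. Genes away from the uninjured level in the same direction at both times numbered 130, with 27 higher (independent lists 4.1) and 103 lower (independent lists 10.6), against a simulated mean of 0.05. That total was 83 and 55 without uninjured library 1 and 2, and 81 and 70 without 21 d library 2 and 3. The simulated values leave out real effects and the independent ones leave out the shared libraries. The comparisons behind the 1069 genes share the 48 h libraries, and those behind the 130 share the uninjured ones. With 3 libraries a group is too small to split, so part of either excess may come from the sharing. Across genes, which are not independent replicates, the log2 fold changes at 48 h and 21 d had a correlation of 0.45, where simulated unchanged groups gave 0.50. Their covariance was 0.829, where the simulation gave 0.48 and the residual variance of the uninjured mean gave 0.576.

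**Figure D3:**
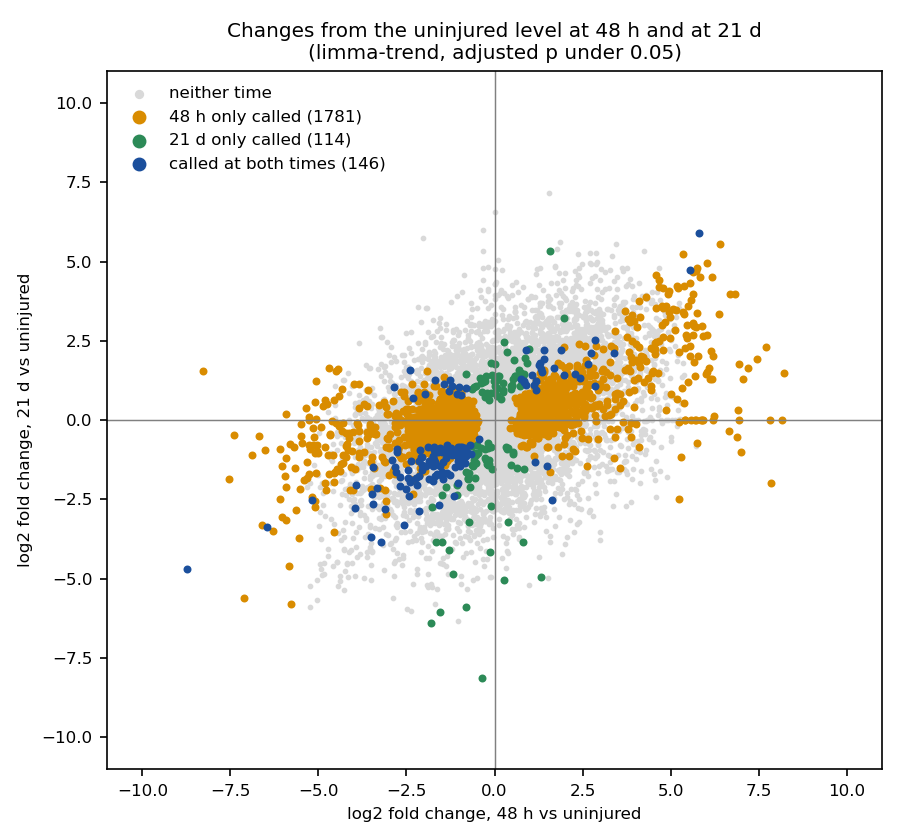
Log2 fold change against uninjured tissue at 48 h (horizontal axis) and at 21 d (vertical axis) for 17891 genes, coloured by the times at which each passed limma at an adjusted p under 0.05. Of these genes, 1781 were called at 48 h but not at 21 d, 114 at 21 d but not at 48 h, and 146 at both times.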

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

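The tests of clock timing, of pituitary RNA and of the matrix genes were chosen only after the result was seen, while the splits of the libraries were set beforehand. So was the glucocorticoid test on targets whose values had not been seen, though values of other targets had been seen by then.

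A set of 16 genes passed in both comparisons with uninjured tissue but in opposite directions. Their change from 48 h to 21 d is the difference of those changes, so its size follows from how the genes were picked and is no separate evidence. The 13 genes lower at 48 h and higher at 21 d than in uninjured tissue had log2 fold changes from 48 h to 21 d of 2.28 for atf3, 3.90 for cited4a, 2.21 for CR354588.1, 1.91 for dusp1, 1.73 for herc1, 1.84 for hif1al2, 2.81 for klf9, 3.98 for lmbr1l, 2.56 for midn, 3.02 for nr1d2a, 2.06 for sgk1, 2.6 for si:ch211-227m13.1 and 2.95 for slc20a1a. The 3 genes higher and then lower had -2.45 for ier5l, -4.13 for slc43a2b and -2.95 for tnfrsf11a. Independent lists would share 5.9 and 7.4 genes in these directions.

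Repressors and output genes of the clock fell at 48 h in 10 of 16 (median -1.46) and rose from 48 h to 21 d in 9. Of 7 glucocorticoid targets picked because their values had been seen, 7 fell at 48 h and 6 rose by 21 d, zbtb16a being the exception (0.30, adjusted p = 0.51). Depending on the hours compared, a different time of day at collection could raise the activating genes of the clock and the nfil3 repressors of the same phase. Of 9 tested at 48 h (median 0.44), 0 rose and 1, nfil3-6, fell (limma camera, unadjusted p = 0.974 with the preset and 0.974 with an estimated correlation). At 21 d against uninjured tissue this list lay higher, with a median of 0.92 and 1 member called (limma camera, unadjusted p = 0.00192, and 0.018 with an estimated correlation). From 48 h to 21 d, 3 of its members rose and 1 fell (limma camera, unadjusted p = 0.0305, and 0.0655 with an estimated correlation). Lower glucocorticoid exposure would lower targets whose values had not been seen, and of 13 tested 3 (errfi1a, trim63b and fbxo32) rose and 4 fell (limma camera, unadjusted p = 0.217 with the preset and 0.311 with an estimated correlation). Neither explanation is excluded or borne out, time of day is not given in the labels, and the ablation itself stays open as untested.

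The growth hormone gene gh1 was higher in uninjured libraries than at 48 h or 21 d. RNA of the pituitary would bring its other hormones, and 4 other hormone genes taken as pituitary markers were compared, prl2, pomcb, fshb and lhb. The lowest uninjured gh1 value, 36019, was 879 times the highest value of any of these 4 in an uninjured library, 41 for pomcb. Whether these 4 genes are abundant in pituitary RNA was not tested, and further pituitary hormones were not compared. The ratio therefore cannot decide the question. No other source was tested, so pituitary RNA and a difference between uninjured and ablated fish both stay open.

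Matrix genes of valve interstitial cells were lower at 48 h. Dilution of resident cells by incoming ones would lower endothelial genes alike. The mean of the matrix list lay below that of the endothelial list by a log2 difference of -1.77 (means -1.69 and 0.08, 27 and 29 genes, permutation p = 2.0e-04). The permutation moved genes between the lists as if they were independent, so its p does not measure the spread between libraries. This gap argues against dilution as the whole cause only if endothelial genes did not respond to the ablation themselves, which was not tested. Loss of matrix-producing cells may lower their genes by a common factor, and falls among the 11 called members ranged from 3.61-fold for dcn to 42.4-fold for lum, a ratio of 11.8. A mixture of cell types gives such a range too, so cell loss and lower expression per cell cannot be told apart.

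For each comparison the 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In each, 1 split, the real one, gave as many called genes, with 1927, 260 and 1768 genes in the order of the report against 0 in the highest other split.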

How the results depend on the processing

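The trimmed-mean, equal-total and quantile scalings, the pseudocounts, the non-robust fit and the array weights were chosen only after the result was seen; the other alternatives were planned. Planned size factors were the deposited scaling itself, and a Wald count test and limma-voom were not run because the values are not counts. Over all alternatives the named genes kept direction and side of the threshold in 3491 cases, lost the call in 137 and gained it in 17, and lists kept theirs in 1180 and lost the call in 116. In 2 further cases, both the ribosomal list without 48 h library 3, the call was lost (adjusted p = 0.91 and 0.609) and the median changed sign. Only lists called in the fit reported above were followed, so these numbers could hold no gained list call. With a replicate block, 16 lists passed at 21 d against uninjured tissue, of which 15 were shared with that fit. The cause of these differences was not tested. The 21 d against uninjured total was 427 with only the 2 groups in the fit, where 250 genes were shared with the 260. With an estimated correlation 5, 0 and 3 lists passed in place of 25, 15 and 19. With a replicate block the totals were 1918, 239 and 1710. Libraries of different groups were also correlated on their deviations from the group means. These correlations ran from -0.02 to 0.03 for libraries with the same number and from -0.04 to 0.05 for other pairs. In 6 libraries the best match had their own number.

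Leaving out each library moved the totals to between 107 and 330 at 21 d against uninjured, 1144 and 1806 at 21 d against 48 h, and 55 and 145 for genes changed in the same direction at both times. Such fits have fewer libraries. Signs turned for these log2 fold changes of named genes, none past the threshold with the turned sign. With equal column totals tgfb3 was 0.22 and notch1b 0.27 at 48 h, tgfb2 0.02 at 21 d, and notch1b -0.12 and tgfb3 -0.09 from 48 h to 21 d. Scaled without mitochondrial, haemoglobin and heart-muscle genes, notch1b was 0.00 at 48 h. With quantile normalization tgfb3 was 0.10 and notch1b 0.27 at 48 h, tgfb2 0.04 and tgfb1b -0.00 at 21 d, and notch1b -0.07 from 48 h to 21 d. Leaving out libraries gave ranges at 48 h of -0.20 to 0.06 for tgfb3 and -0.32 to 0.22 for notch1b. At 21 d they were -0.21 to 0.03 for smad3a, -0.22 to 0.18 for tgfb2, -0.18 to 0.30 for tgfb1b, -0.04 to 0.19 for myl7, -0.04 to 0.22 for tgfb3, -0.20 to 0.36 for smad3b and -0.10 to 0.35 for notch1b. From 48 h to 21 d notch1b ran from -0.09 to 0.44. The ribosomal list's median ran from -0.04 to 0.44 at 48 h and from -0.39 to 0.08 from 48 h to 21 d.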

Other observations

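Both lists described here were drawn up, and the test of the insulin-like growth factor genes chosen, only after the result was seen.

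Genes of the growth hormone, insulin and insulin-like growth factor axis fell at 48 h in 11 and rose in 1 of 29, the 1 being igf2b, with a median log2 fold change of -0.84. At 21 d against uninjured tissue 2 fell, and from 48 h to 21 d 12 rose and 1 fell. A hypothesis is that transcripts of the axis were lower as a set at 48 h. Because gh1, igf1, igfbp1a, igfbp3, irs1, irs2b and foxo1a prompted it, it was tested on the other 22 members, of which 4 fell and 1 rose (limma camera, unadjusted p = 0.0101, and p = 0.0849 with an estimated correlation). The hypothesis may hold, but these values do not settle it. The list mixes hormones, receptors, binding proteins and transcription factors, so a common direction of transcripts cannot tell whether signalling rose or fell.

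Known targets of the hypoxia-inducible factors, 26 genes of which 16 also stand in the hypoxia list, fell in 18 and rose in 1 at 48 h (median -1.16). At 21 d 11 fell and 0 rose (median -0.91), and from 48 h to 21 d 4 rose and 4 fell.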
